A study of Mus musculus with 12 samples.

How the data were processed

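Total RNA from mouse serum was extracted with TRIzol and made into libraries with a stranded total RNA kit, per the labels' protocols; file names call the material blood, and the labels' word, serum, is used here. The deposited files hold 1 column of whole-number counts per gene symbol and were taken as read counts, not normalized, from the values. The submitters' processing notes name Trim Galore, HISAT2, StringTie and the mouse build mm10, with no version, role or order. The annotation, the counting step and its strand setting are not given in the sources used here, and if the authors took the counts from StringTie they derive from transcript coverage.

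Each of the 12 files has 53546 rows, and 0 rows name no gene. The files of colorectal cancer replicates 5 and 6 are identical in every row, while the closest other pair differed in 12482 rows. The repeated file was counted once, which gave 11 libraries, 5 of colorectal cancer and 6 normal. Symbols were matched to GENCODE release M21, an annotation of mm10, and 49972 had a single position. Positions are those of the annotation, 1-based, and the files themselves carry none.

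The depth per library ran from 2889205 to 20774889 counts. A row at 0 in all libraries allows up to 0.025 CPM over the summed total (3 counts of 119956737), and in the smallest library alone up to 1.04, which covers counting error only. Rows are per gene, and reads shared by paralogs, pseudogenes and overlapping genes cannot be assigned from these counts.

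Rows were filtered with edgeR's filterByExpr by group, scaled with TMM factors and tested with edgeR 4.0.16 (glmQLFit with robust estimation and glmQLFTest, R 4.3.3), with group as the only term and Benjamini-Hochberg adjustment over 9565 rows at 0.05. Values per library are TMM-scaled counts per library total (CPM). Gene lists with at least 5 tested members were tested with camera (limma 3.58.1, preset correlation 0.01), and fry and camera with an estimated correlation were alternatives. The 35 lists cover blood cell types, tissues that blood should not hold, and pathways; they have 876 distinct members, of which 332 were at 0 in all libraries and 294 were tested. Library measures were compared with two-sided exact permutation tests over 462 splits. Python 3.11.15, SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9 were used for tables and plots.

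The genes to name followed a rule set before the data were examined. It took the 8 largest rises and 8 largest falls past the threshold with parted groups and at least median expression, leaving out clone and predicted-gene names, then the 4 smallest p-values in each direction. From every list it took up to 2 rising and 2 falling members past the threshold, or where none passed the 2 most abundant, and all sex-linked genes. This gave 87 genes, of which 31 passed. Genes named outside the rule are marked as such, and some genes that the rule took are given only within their list's count or are not reported here.

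The procedure was tested on simulated data drawn from the means and library sizes of this comparison. With 200 of 9565 genes changed 2-fold or 4-fold, and a further list of genes raised by less than 2-fold, 3.7% of the calls were unchanged genes. It recovered 40.5% of genes changed 2-fold and 79% of genes changed 4-fold. The simulation gave each gene a single mean and no row that switches between sets of libraries, so its error rate need not hold for these data.

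Alternatives set before the data were examined were DESeq2 size factors within edgeR, DESeq2 1.42.0, no filter, a mean of 10 CPM, globin or mitochondrial rows left out, the replicate number as a block, the repeated file kept, each library left out, a fold above 1.5 tested, and the mean of 4 cell type lists as covariates. Alternatives for normalized units did not apply, since the files hold counts. Chosen after seeing the data were leaving out the row named Olfr648, with and without TMM factors, keeping only the 6 libraries with high counts in it, or that division as a covariate, thinning each library to 2885958 counts, summing overlapping same-strand rows, and keeping only rows in stretches with few genes at 0. Positions of rows were compared by moving rows along their chromosome and counting how many then lay on exons of another gene; several such scans were looked at before the test that is reported.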

Results

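RNA was sequenced from mouse serum samples of 2 groups, normal animals and animals with colorectal cancer, with 6 samples per group in the labels. The labels call the samples biological replicates and the series text speaks of different mice. The files of colorectal cancer replicates 5 and 6 held identical values and were counted as 1 sample, named replicate 6 here, which left 5 colorectal cancer libraries against 6 normal ones. Each library lists whole-number counts for 53546 gene symbols, of which 21309 were above 0 in at least 1 library. Totals ran from 2889205 to 20774889 counts per library. The row named Olfr648, an olfactory receptor gene, held 7969078 to 17324370 counts in 6 libraries (2 normal, 4 colorectal cancer) and 3247 to 5150 in the other 5. High libraries made up 4 of 5 in colorectal cancer and 2 of 6 in normal serum, a difference that did not pass (two-sided Fisher's exact p = 0.242) and that so few libraries cannot exclude. Without that row the totals lay between 2885958 and 7033966.

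**Figure D1:**
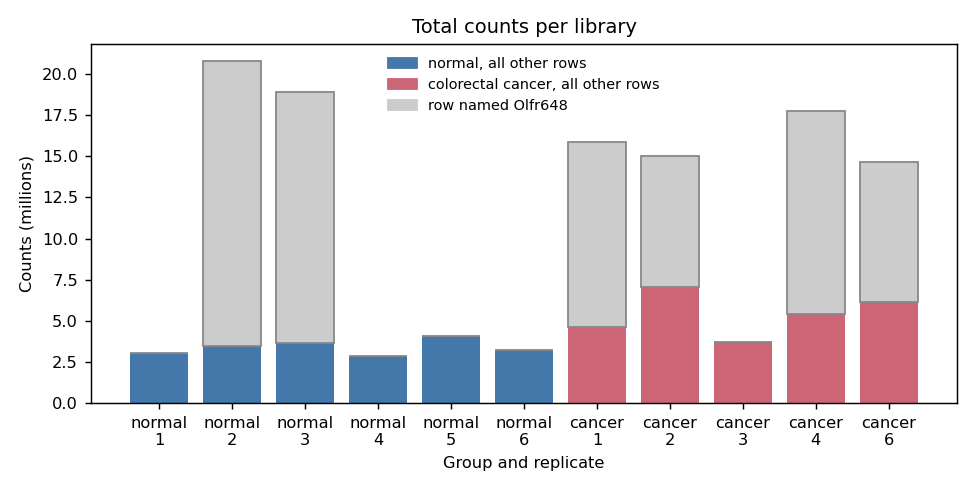
Total counts per library, one bar per library (normal replicates 1 to 6 and colorectal cancer replicates 1, 2, 3, 4 and 6), with the counts of the row named Olfr648 stacked in grey. The 6 tall bars owe their height to Olfr648, which held at most 5150 counts in the other 5 libraries.

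Gene symbols are given as the rows name them, and the names carry a measured limit. Of 183 ribosomal protein, proteasome and oxidative phosphorylation genes, which nearly all cells use, 73 (39.9%) were listed at 0 in every library. They were 30 cytosolic ribosomal protein genes, 29 nuclear-encoded oxidative phosphorylation genes and 14 proteasome genes. Among all protein-coding rows 42.2% were at 0 throughout. The beta-globin genes Hbb-bs and Hbb-bt and the ubiquitin gene Ubb were among the rows at or near 0, with 0, 0 and 4 counts summed over the 11 libraries. Zeros were not spread evenly along the genome. When protein-coding genes were taken in 443 runs of up to 40 neighbours, 13 runs had at most 15% of their genes at 0 and at least 40% at 100 counts or more, bounds chosen after the values were seen. Most of the 13 adjoin each other in a single stretch of chromosome 4, from 3549041 to 59438633. The first runs of chromosomes 6, 9 and 18 are also among them, so the 13 are not separate places spread over the genome. A count below refers to the row of that name, and it is not established that a row outside those 13 runs measures the gene of its name. Nor is it established for rows inside them. The runs were picked on these same values, and the check on their essential genes, given below, did not pass.

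The comparison of colorectal cancer with normal serum asks which transcripts differ in animals carrying the tumour. Casp4, an inflammatory caspase that senses bacterial lipopolysaccharide, rose 2.54-fold, from 73.7 ± 19.6 to 187 ± 19.6 TMM-scaled CPM, a normalised read count (SD, n = 6 normal and 5 colorectal cancer). Casp1, the caspase that matures interleukin-1 beta, rose by 0.72 on the log2 scale beside it on chromosome 9, and was named after its values were seen. Of 10 tested erythroid genes 2 fell: Hemgn went from 51.0 ± 10.7 to 15.3 ± 5.82 and Tspan33 from 469 ± 103.6 to 161 ± 50.4 CPM. Pabpc1, which encodes the main cytoplasmic poly(A)-binding protein, fell 2.38-fold from a high level, 5150 ± 1046 to 2162 ± 446 CPM. Casp4, Casp1, Hemgn and Tspan33 lie in the runs with few genes at 0, and Pabpc1 lies in a run with 21.1% at 0.

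Across 9565 tested rows, 54 were higher and 139 lower in colorectal cancer by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05 (two-sided). At an unadjusted p under 0.05 the counts were 547 higher and 540 lower. The rows called higher had a median log2 fold change of 0.93 (quartiles 0.67 and 1.42), and the rows called lower a median of -1.18 (quartiles -1.46 and -0.77). In 46 of the higher and 124 of the lower rows no library of one group overlapped the other group. Over all tested rows 3.64% were parted in this way, where chance gives 0.433%. Higher rows made up 28.0% of the calls. With the row named Olfr648 left out and libraries scaled by their totals alone, 1383 rows were higher and 100 lower, so that 93.3% of the calls were higher, and the median log2 fold change of all rows moved from 0.04 to 0.43. Changes are reported relative to the main scaling. The number of higher rows depended on single libraries: it was 20 without normal replicate 2, 35 without normal replicate 6, and 16, 27, 20 and 16 without colorectal cancer replicates 1, 2, 4 and 6. With 1 library left out, the rows called higher kept a median log2 fold change from 0.841 (without normal replicate 1) to 1.01 (without normal replicate 4), all with the same sign where tested. The fit on all 11 libraries had picked these rows, and in 46 of them the groups did not overlap. The kept sign and size are therefore no separate support for them. The lower rows numbered 89 without colorectal cancer replicate 4. With the mean of the erythroid list as a covariate no row was called (238 higher and 360 lower at an unadjusted p under 0.05), and with the neutrophil maturity list 1 higher and 0 lower rows were called. The 139 lower rows had a median log2 fold change of -0.522 with the former covariate and -1.16 with the latter, and the 54 higher rows 0.70 and 0.744, all 54 with the same sign. With the Olfr648 division as a covariate 13 rows were higher and 68 lower, and the medians were 0.812 and -1.08.

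Gli3, a transcription factor of hedgehog signalling, was among the largest rises in rows with parted groups and went from 2.01 ± 1.76 to 29.6 ± 21.8 CPM. Its row was the 1 called row among 67 that switch between near 0 and many counts, lies in a run with 56.4% of genes at 0, and lost its call in 7 of 30 settings, among them the Olfr648 division as a covariate. Ddx6, an RNA helicase of processing bodies, rose by 1.87 (SE 0.34) on the log2 scale. Wnt10b, a secreted Wnt ligand, rose by 1.78 (SE 0.26; lower in all 6 normal libraries than in all 5 colorectal cancer ones). Serhl, Mxd1, Pithd1 and Sh3d21 rose by 1.67, 1.61, 1.54 and 1.42, but each lost its call in many settings: 15 of 30, 14 of 30, 17 of 29 and 15 of 30. Leaving out colorectal cancer replicate 1, 4 or 6 or normal replicate 2 or 5 ended the call of each of these 4 genes. Leaving out normal replicate 1 did so for all but Mxd1, normal replicate 6 for all but Pithd1, colorectal cancer replicate 2 for all but Serhl, and normal replicate 3 for Pithd1 alone. Where lost in this way their adjusted p lay between 0.0505 and 0.118 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The smallest p-values among the higher rows were those of Casp4 (adjusted p = 0.00512 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), Wnt10b, Olfr2 and Hdac4. Hdac4, a histone deacetylase, rose by 0.74, and Olfr2, a receptor gene on the same chromosome as Olfr648, by 0.69. Ddx6 and Hdac4 overlap genes with counts on both strands and Serhl on the other strand, and since the strand setting of the counting is not given in the sources used here, their reads cannot be told from those of their partners. Of the genes of this paragraph Casp4 alone lies in the runs with few genes at 0.

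Among the falls, Cenpb, which encodes a centromere protein, had the smallest p-value of all rows (log2 fold change -1.33, SE 0.15, adjusted p = 0.00512 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Ybx3, a cold shock domain protein that binds RNA, fell by 1.66 (555 ± 88.6 to 176 ± 63.3). Galnt6, a glycosyltransferase, fell by 0.76. The largest falls were those of Anks1b, Ccdc15, Ccdc71, AI506816, Olfm5, Zfp60, Nemf and Fam220a, with log2 fold changes from -1.99 to -1.75. Fam220a was the most abundant of them at 3421 ± 617 CPM in normal serum and 1015 ± 510 in colorectal cancer. Cenpb overlaps Spef1 on the same strand, and Galnt6, Ccdc15, Ccdc71 and Nemf also overlap other genes with counts. The calls of AI506816 (without normal replicate 1 or colorectal cancer replicate 1, 2 or 6) and Nemf (without colorectal cancer replicate 1, 2 or 4) were lost, with adjusted p up to 0.0921 and 0.0569 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Fam220a has no single position in the annotation, and none of the other genes of this paragraph lies in the runs with few genes at 0.

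**Figure D2:**
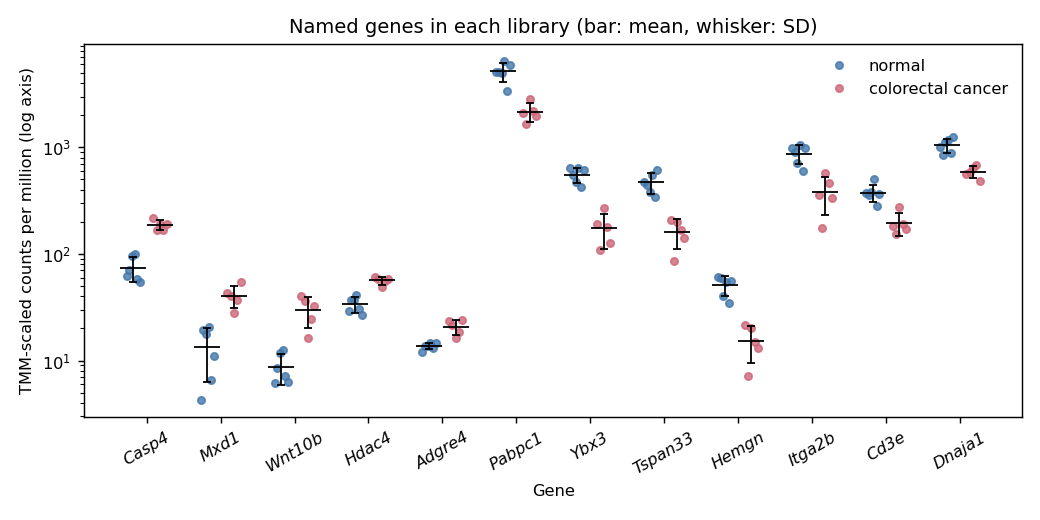
TMM-scaled CPM (log axis) of 12 named genes in each of the 6 normal and 5 colorectal cancer libraries. Points are libraries, bars the group mean and whiskers the SD; Casp4, Mxd1, Wnt10b, Hdac4 and Adgre4 sit higher in colorectal cancer and the other genes lower.

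Among the rows in the 13 runs with few genes at 0, 368 were tested, and 4 of these were higher and 18 lower in the test over all rows. The 4 higher were Casp4, Casp1, Cpne3 and Map3k8, and outside Casp4 they were named after their values were seen. Cpne3 rose by 0.61 and Map3k8, a kinase of inflammatory signalling, by 0.50 on the log2 scale. Several of the 18 lower rows were abundant, such as Dcaf12 at 4048 ± 832 and Ube2r2 at 2638 ± 540 CPM in normal serum, against 1407 ± 616 and 947 ± 383 in colorectal cancer. Tmod1, which caps actin filaments in the red cell skeleton, fell by 1.69, and Bag1, a partner of Hsp70, by 1.01. These genes too were named after their values were seen. The heat shock gene Dnaja1 and the respiratory chain gene Ndufa4 are among the 18. Dcaf12, Tmod1, Bag1, Hemgn and Dnaja1 all lie in the single stretch of adjoining runs on chromosome 4.

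Of 35 gene lists fixed before the data were examined, 31 had at least 5 tested members. By camera with a preset correlation of 0.01, no list was higher and 2 were lower. The list of platelets and megakaryocytes was lower (adjusted p = 0.00625; adjusted p = 0.193 with an estimated correlation). Of its 6 tested members 1 fell, Itga2b, the integrin alpha chain of the platelet fibrinogen receptor (log2 fold change -1.20, SE 0.26, 874 ± 178 to 379 ± 148 CPM). Itga2b lost its call in 15 of 30 settings, among them without normal replicate 1, 2, 4 or 6 or colorectal cancer replicate 1, 4 or 6 (adjusted p 0.0624 to 0.108 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and it lies outside the runs with few genes at 0. The other 5 did not pass, while 3 were lower when adjusted over the list alone, and 11 of the 25 members were at 0 in all libraries. The list of erythroid cells was lower (adjusted p = 0.0265; adjusted p = 0.212 with an estimated correlation). Of its 10 tested members 2 fell, Hemgn and Tspan33, 8 did not pass, and 3 were lower when adjusted over the list alone; its median log2 fold change was -0.10 and its mean -0.50. Among the members that did not pass, Add2, of the red cell skeleton, had 3.57 CPM in colorectal cancer and 12.8 in normal serum (adjusted p = 0.0507 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The alpha-globin gene Hba-a1 had 4.81 and 4.90 CPM, Epb42 5.11 and 4.90 and Gata1 0.906 and 0.771, levels too low to say much. These 4 genes were named after their values were seen. The erythroid list was not called without normal replicate 1, without normal replicate 2 or without normal replicate 4, nor with the Olfr648 libraries as a covariate or with no low-count filter. With rows at a mean of 10 CPM or more neither list was called. The erythroid list could not be called there: of its tested members only Hemgn and Tspan33 reach that mean, under the 5 that a test needs.

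No list of granulocyte or monocyte genes was called by camera. The neutrophil maturity list had 1 of 6 tested members higher, Mxd1, a partner of Max (13.3 ± 6.98 to 40.5 ± 9.53 CPM, a call lost in 14 of 30 settings), and the same number adjusted over the list alone. Of the granule and precursor list none of 5 passed over all genes tested, and 1 was higher adjusted over the list alone. Its member Mmp8, a neutrophil collagenase in the runs with few genes at 0, had 206 ± 119 CPM in normal serum and 558 ± 120 in colorectal cancer (adjusted p = 0.134 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). By fry, which tests a list on its own, both lists were higher (adjusted p = 0.0302 for each), and camera gave adjusted p = 0.459 and 0.404. Among 9 tested monocyte and macrophage genes Adgre4 rose by 0.60 on the log2 scale, and 1 was higher adjusted over the list alone; without normal replicate 1, 2, 3, 5 or 6 or colorectal cancer replicate 1, 2, 4 or 6 its call was lost (adjusted p 0.0584 to 0.115 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). None of 13 tested myeloid suppressor genes passed, and 0 did adjusted over the list alone.

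Among lymphocyte markers Cd3e, a chain of the T cell receptor complex, fell from 377 ± 71.3 to 195 ± 47.2 CPM. It was the one T cell gene of 11 to pass, also adjusted over the list alone, and the list was not called (camera adjusted p = 0.24). The T cell list was called lower with no low-count filter, without normal replicate 4, and with Olfr648 left out and totals alone. None of 10 B cell genes passed: Pax5, a B cell transcription factor, had 725 ± 146 CPM in normal serum and 716 ± 37.8 in colorectal cancer, and Cd72 274 ± 38.7 and 254 ± 42.8; both lie in the runs with few genes at 0. None passed among 4 plasma cell, 7 NK cell, 5 dendritic cell, 6 eosinophil, basophil and mast cell, 4 blood stem cell and 8 T cell checkpoint genes, with 0 in each adjusted over the list alone.

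Of the stress and housekeeping lists, 1 of 7 immediate early and heat shock genes fell, Dnaja1, an Hsp40 co-chaperone (1046 ± 157 to 589 ± 77.8 CPM), with 1 higher and 1 lower adjusted over the list alone. Of 11 proteasome genes Psmd3 fell by 0.83, and of 26 nuclear-encoded oxidative phosphorylation genes Ndufa4 fell by 0.60, though not past the test without colorectal cancer replicate 2 (adjusted p = 0.0501 by edgeR); each was the one member lower adjusted over the list alone. None of 22 ribosomal protein genes passed, Rps20, in the runs with few genes at 0, standing at 1535 ± 145 CPM in normal serum and 1454 ± 225 in colorectal cancer. None of 13 mitochondrially encoded protein genes passed either. The mitochondrial ribosomal RNA mt-Rnr2 is not on that list and fell, as given below. Cdkn1a, a cell cycle inhibitor on the glucocorticoid list, had 39.7 ± 14.7 and 74.1 ± 15.03 (adjusted p = 0.117 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). It was the 1 of 7 on that list higher adjusted over the list alone. No member passed, over all genes or adjusted over the list alone, among 14 interferon-stimulated, 8 NF-kB and cytokine, 5 MHC class I, 6 MHC class II, 10 cell cycle, 10 hypoxia and glycolysis, 8 heme and iron and 8 unfolded protein response genes.

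No row named for a gene of tumour or other tissue passed the test. Of 7 tested intestinal epithelial genes, 7 Wnt targets and 12 colorectal cancer driver genes none passed, over all genes or adjusted over the list alone. Lgr5, the intestinal stem cell receptor and a Wnt target, had 119 ± 7.36 CPM in normal serum and 124 ± 13.8 in colorectal cancer, and the mucin gene Muc2 12.5 ± 2.42 and 10.3 ± 2.73; both lie outside the runs with few genes at 0. The same held for 2 liver, 6 fibroblast and endothelial and 4 muscle and skin genes. Of 6 sex-linked genes none passed, and 1 was higher adjusted over the list alone; the Y-linked Ddx3y stood at 297 ± 23.6 and 280 ± 39.0 CPM, and Xist at 13.5 ± 2.68 and 14.4 ± 2.27.

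More rows were above 0 in colorectal cancer, 13931 ± 1143 against 11338 ± 660 (SD, n = 5 and 6; two-sided exact permutation p = 0.00217 over 462 splits, adjusted p = 0.0108 over 5 measures). Total counts (p = 0.307), the percent of the total in the 10 highest rows (p = 0.535), in alpha- and beta-globin rows (p = 0.944) and in mitochondrial rows (p = 0.234) did not differ by the same exact test. Without the row named Olfr648, totals were 5391619 ± 1290785 in colorectal cancer and 3399245 ± 444113 in normal serum (two-sided exact permutation p = 0.00433), a measure added after the data were seen, so more rows above 0 went with more counts. The 10 highest remaining rows held 27.4% ± 1.53 and 36.8% ± 2.35 (two-sided exact permutation p = 0.00217).

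Casp4 lies on chromosome 9 from 5308828 to 5336783, Hemgn on chromosome 4 from 46393989 to 46413506, Tspan33 on chromosome 6 from 29694222 to 29718559, Pabpc1 on chromosome 15 from 36595661 to 36609668 and Itga2b on chromosome 11 from 102453297 to 102470122 (mm10). Each value is the count over a whole gene row, and the files do not part exons from introns. Olfr648 lies on chromosome 7 from 104177598 to 104183392, and Hbb-bs, at 0 in all libraries, begins at 103826534.

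**Figure D3:**
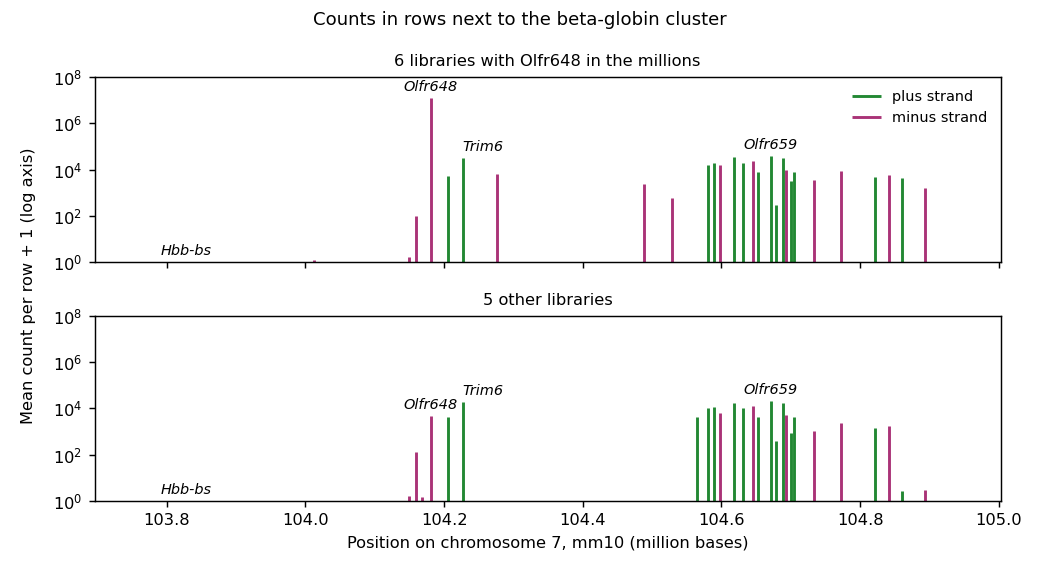
Mean count per row plus 1 (log axis) along chromosome 7 in mm10, with lines coloured by strand, for the 6 libraries with high Olfr648 counts (top) and the 5 other libraries (bottom). Hbb-bs is at 0 in both, and Olfr648, Trim6 and Olfr659 stand above it in both.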

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

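Of the tests in this part, those on the receptor rows were chosen only after the result was seen. In each group, the highest or lowest library was set against the others by the size of its gap, which chance exceeds in about 1 in 20 groups; 11 of 184 groups did so, where chance gives 9.2.

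Normal replicate 6 stood apart for Eaf2 (0.603 CPM against 3.18 to 6.58 in the others), Clec9a (717 against 383 to 444) and Stat2 (210 against 253 to 268). Normal replicate 4 was low for Ccr3 (36.7 against 63.0 to 76.6), and normal replicate 3 high for Pdgfrb (18.5 against 11.7 to 13.5). Colorectal cancer replicate 1 was low for Pik3ca (0.873 CPM against 65.1 to 91.7) and for Mb (1.26 against 13.7 to 23.97). Colorectal cancer replicate 3 was high for mt-Cytb (6077 against 5614 to 5685). The same library was low in total counts (3733040 against 14647763 to 17751210) and in the percent of the total in the 10 highest rows (26.2 against 66.0 to 79.2), and high in the percent in globin rows (0.00895 against 0.00232 to 0.00407). It is the one colorectal cancer library without a high Olfr648 count, and those totals include that row.

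Some rows named for olfactory receptor genes were among the most abundant. Within 2 Mb of Hbb-bs, 16 of 156 receptor rows (10.3%) held 1000 counts or more, against 9 of 1239 (0.726%) elsewhere (two-sided Fisher's exact p = 2.43e-10, over rows that are not independent). Sharing of reads between receptor paralogs alone does not account for the stretch as a whole, because 10 rows of other genes there also held 1000 counts or more. Several of these carry Trim or Usp17l names, which recur in the stretch, so sharing among repeated genes in general is not excluded. Reads of the beta-globin locus entered under its neighbours' names are a candidate explanation that the position of these rows leaves open. Rank correlations of their counts with exon length ran from 0.358 to 0.94. In the libraries with high Olfr648 counts, Olfr659 (4842 exon bases) held a mean of 39437 counts. Gm6593 (1135 bases), on the other strand, held 9659. Olfr660-ps1 (375 bases) held 291 and Olfr662-ps1 (396 bases) 3227, so not every row went with length. The rows named here were picked after their values were seen. Whether such counts are reads of separate genes was not tested. No biological explanation was tested.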

How the results depend on the processing

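Tests that leave out or adjust for the row named Olfr648, thin counts, sum overlapping rows or keep only stretches with few genes at 0 were chosen after seeing the data; the others were planned. Against 54 higher and 139 lower rows, DESeq2 gave 148 and 217, a mean of 10 CPM 82 higher, the repeated file kept 112 higher, and a fold above 1.5 tested 1 and 0 (157 and 182 at an unadjusted p under 0.05). With list means as covariates, B cells gave 30 higher, T cells 83 higher, neutrophil maturity 1 and 0, and erythroid cells 0 and 0. With Olfr648 left out and totals alone 1383 rows were higher. Only the libraries with high Olfr648 counts gave 34 and 27, that division as a covariate 13 and 68, and only rows in stretches with few genes at 0, adjusted over those rows, 13 and 23, where fewer rows were tested. Leaving out 1 library gave 16 to 67 higher and 89 to 139 lower rows. With the replicate number as a block 6 were higher and 59 lower; the numbers do not pair the samples (correlations of same-numbered libraries from -0.072 to 0.026). The other settings stayed within 1.5 times the main counts, thinned counts among them (65 and 138).

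No list was higher by camera, 2 were by fry, and 1 was with Olfr648 left out and totals alone. Of 2 lists lower, 0 remained called at a mean of 10 CPM and 0 with an estimated correlation. The erythroid list kept too few members for a test at a mean of 10 CPM, so that is not a lost call. With the Olfr648 division as a covariate 1 was lower, and 1 to 2 were lower with 1 library left out. Without normal replicate 4 and with no filter the T cell list took the place of the erythroid one. Among values of named genes 2338 kept their side of the threshold (135 of them with another sign, past the test in neither setting), 229 no longer passed, 18 newly passed and 3 passed with the opposite sign: Stat2 (0.37), mt-Cytb (0.29) and Uty (0.38), with Olfr648 left out and totals alone. That scaling moves all rows up, by a median shift from 0.04 to 0.43, so values near 0 change sign by its construction. The 60 values of library measures stayed on their side. Apart from the smaller number of rows or libraries where that applies, the cause was not tested.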

Other observations

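Of the tests in this part, those of the rows displaced by a shift, of the nearest gene above 0, of the switching rows, of the runs with few genes at 0, of the falls and of the other splits were chosen only after the result was seen. Genes named in the next paragraph were likewise chosen after their values were seen.

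Among rises outside the rule was that of a receptor of myeloid cells. Olr1, a scavenger receptor for oxidised lipoprotein, had 189 ± 73.7 CPM in normal serum and 398 ± 55.6 in colorectal cancer, past the test. The mitochondrial ribosomal RNA mt-Rnr2 fell by 0.81 on the log2 scale, from 62020 ± 12360 to 35280 ± 6959. Hells, Palb2 and Gm49528 were called higher with all normal libraries at 0, at 3.86, 1.16 and 4.71 CPM in colorectal cancer. Of the called rows 0 were at 0 in all colorectal cancer libraries. Normal libraries held fewer counts on average without the row named Olfr648, so a 0 is easier to reach there. These low rows also lie outside the runs with few genes at 0.

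The zeros in essential genes were weighed against several ways in which counts could come to stand under another name. Nearest same-strand genes of the 73 genes at 0 were compared with other-strand ones (mean log2 difference 0.0621, SE 0.4, permutation p = 0.881), which decides nothing, since the strand setting is not given and the median neighbour was at 0 on both strands; the nearest genes above 0 left it open too (0.288, SE 0.453, permutation p = 0.528), and so did pseudogene numbers (difference -0.41) and 67 rows that switch between near 0 and many counts, 7 of which were steadied by same-strand and 9 by other-strand overlapping rows (exact McNemar p = 0.774). For gene positions of another genome build, a test set beforehand met the bound written against it. At 1 shift per chromosome chosen on ribosomal protein genes, 1 of 42 proteasome and oxidative phosphorylation genes at 0 was covered by rows of 100 counts or more, and 1 at the mirrored shift, with an upper exact 95% bound of 12.6%. That test bears only on a single shift per chromosome, and it decides nothing about shifts that change along one. Windows of chromosome 11 below gave 109.2 and 114.2 kb, but those shifts are not established and do not void it. A looser form, chosen after several scans of the same rows, let each of 41 windows of 20 Mb have its own shift. Of 862 rows not used to choose it, 46.9% lay on exons of another gene at the shift and 39.4% at the mirrored shift (exact McNemar p = 0.00151). Rows of a window share its shift and are not independent, which the McNemar tests here ignore. In 5 windows the shift chosen on the remaining rows lay within 5 kb, against 0.851 with windows shuffled (one-sided permutation p = 0.00086, computed after the 5 were seen). Rows at 0 showed 24.8% and 24.3% (exact McNemar p = 0.854), with 1 of 38 windows within 5 kb against 0.341 (one-sided permutation p = 0.294), yet the difference in excess, 7.33 percentage points (SE 4.48, two-sided permutation p = 0.111), did not pass, so displaced rows and the spacing of genes cannot be told apart, and a local displacement of row names may stand only as a hypothesis.

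At such shifts some rows meet genes that blood is known to express. The row Mmgt2, with 2151687 summed counts, met Ubb at a shift of 109 kb, and the row Itga2b met Slc4a1, the red cell anion exchanger, at 114 kb. Wnt10b met Ddx23 at 128 kb and Zfp60 met Blvrb at 301 kb. These 4 were picked from many rows after the overlaps were seen. Other rows met other genes or none: in the windows of Zfp60 and Wnt10b, the row Blvrb met Cyp2t4 and the row Serhl met no other gene. The windows of Itga2b, Wnt10b and Zfp60 are among the 5 named above; that of Mmgt2 is not, though the next window on chromosome 11 is, at 109.2 kb. The row Olfr648 met Olfr68, not a beta-globin gene, at the shift of its window, 406 kb, which is not among the 5. Chosen on either part of that window's rows, the shift was 356.8 or 406.6 kb, and Hbb-bs lies 350 kb from the row. At 356.8 kb fewer of the rows not used to choose it lay on exons of another gene than at the mirrored shift. The closeness of 356.8 to 350 kb is therefore no support for beta-globin reads in the row Olfr648. No shift is established for this window, so the overlap at 406 kb does not speak against such reads either. In the 13 runs with few genes at 0, none of 6 essential genes was at 0, against 73 of 176 (41.5%) elsewhere, a difference that did not pass (two-sided Fisher's exact p = 0.0825; the runs were chosen without those genes).

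The falls of the rows called lower, abundant or not, were set against depth, scaling and the Olfr648 libraries. The 139 rows called lower kept a median log2 fold change of -1.19 with counts thinned to a common total. It was -0.789 with totals alone and -1.08 with the Olfr648 division as a covariate. Thinning lowers counts without moving the fold change to be expected, so it decides nothing about depth. Totals alone move all rows up together, so that value shows only that this choice of scaling does not undo the falls. The last value argues against the Olfr648 division as the whole cause, for rows that the main fit had picked. Fewer erythroid cells among the cells sampled may remain open: the erythroid list was lower by camera with a preset correlation, but had adjusted p = 0.212 with an estimated one. With its mean as a covariate the median of the rows called lower moved to -0.522, the largest move of the 4, though the list holds called rows and follows the groups itself. A difference in the tumour-bearing animals themselves was not tested apart from these.

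In 100 drawn splits of the 11 libraries, the real one included, 1 gave as many higher genes (54 in the real split, at most 1 in the others). For lower genes it was also 1 (139, at most 1). These counts argue against a random division of the libraries as their source. A share of 1 in 100 is the least that this draw can give. The test cannot part group from depth, since totals without the row named Olfr648 also differed between the groups. For lists, 3 of 100 splits, the real one included, gave as many lower as the real 2 (highest other 2), and since other splits reached it and both calls are lost with an estimated correlation, chance is not put aside here. No list was higher in the real split, and all 100 splits reach a count of 0 (highest other 2), which says nothing.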
